A study of Chlamydomonas reinhardtii with 24 samples.

How the data were processed

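RNA of Chlamydomonas reinhardtii was measured in 24 libraries. Per the labels' protocols, cells were grown mixotrophically in acetate medium under continuous light of 20 µmol photons per square metre and second, moved to minimal medium for at least 1 h, and then kept under narrowband UV-B tubes at 0.2 mW per square centimetre behind a filter with half-maximal transmission at 311 nm. The series text gives 1 h of exposure. Controls stood behind a 360 nm filter that blocks UV-B, and both received the same dim white light. RNA was extracted with a column kit (RNeasy) and a DNase step, and libraries were made with a stranded poly(A) kit (Illumina TruSeq), per the labels' protocols. The mutants are strains whose labels carry names of the Chlamydomonas insertion library, 1 strain per mutated gene. Groups and replicate numbers (1 to 3 in each of the 8 groups) were taken from the sample titles, and no other information was used to place a library.

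The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalized, with a column per library and 14621 genes. Per the submitters' processing notes, bcl2fastq 2.20.0, STAR 2.7.10b, HTSeq 0.11.3 and edgeR 3.42.4 were used, with no role given. The identifiers in the table carry the suffix of annotation version 6.1. The strand setting of the counting, the treatment of reads that match several places, and any removal of genes before deposit are not given in the sources used here. Reads of near-identical copies (LHCSR3A and LHCSR3B, PSBS1 and PSBS2, the LHCBM genes, HSP22E and HSP22F) may therefore be split or missing, and antisense overlaps cannot be excluded. The kit selects poly(A) RNA, so organelle transcripts are hardly covered, and none is named in the text.

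Gene names came from locus identifiers written down before the data were examined, as were the design of each test, the alternatives and the gene lists. The RefSeq gene table used here is of assembly v5.5 and holds 0 symbols, so the names could not be checked against it. The locus number of 13245 genes of the count table occurs in it. No coordinates are printed, since the builds differ and no genome was used here. Of 149 list members with a locus, 139 were found in the table and 138 tested. Members not analysed here include ELI3, HLI1, LHCB4, PSBR, PSB27, PSB28, PSAG, CHYB1, HSP22A and HSP22C, and 4 lists written without loci (DNA repair, gamete markers, intraflagellar transport, cytosolic ribosomal proteins) were not analysed here.

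Library totals were 19267700 to 27686700 counts. Genes at 0 in every library (126) and genes below edgeR's filterByExpr limits (minimum count 10, minimum total 15, by group) were left out, which left 13613. Counts were scaled by TMM (factors 0.670 to 1.20), fitted with 1 mean per group over all 24 libraries, and compared with edgeR's quasi-likelihood F test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3) in 11 comparisons. These were UV-B against no UV-B in each genotype, the difference of that effect between each mutant and WT and between hy5 and co, and each mutant against WT without UV-B. P-values were adjusted by Benjamini and Hochberg over all genes tested and called under 0.05, and the SE of a log2 fold change is its size divided by the square root of F. CPM values use the scaled library sizes, with the SD over 3 libraries.

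The 16 gene lists were tested in each comparison with limma's camera at a preset correlation of 0.01 and with an estimated correlation, two-sided, with adjustment over lists. Fry was run beside them, a test of whether a list moves one way on balance that does not compare it with other genes. It gave adjusted p = 0.000427 for the PSII subunits with UV-B in WT, the only fry value given here. The camera call of that list was lost with an estimated correlation (adjusted p = 0.266). Genes named in the text were chosen by a rule written before the data were examined. It takes the mutated genes, every measured member of the UV-B signalling, qE and LHC-like lists, the 4 members of each other list with the smallest adjusted p in WT, and the genes with the largest changes at a mean CPM of 1 or more, of which at most 2 unnamed identifiers each way are printed. The rule's exceptions are said where they occur. The share of the WT response in each mutant was measured in libraries held out by replicate number, so that no library both chose and measured a gene.

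The script was first tested on simulated counts with known changes. In the WT comparison, over 13550 genes, 5 of 134 calls were false, and in the comparison of hy5 with WT without UV-B 39% of 2-fold and 86% of 4-fold changes were recovered. Replicate numbers were checked for pairing through the correlation of deviations from the group means of the groups compared. They counted as paired where all 3 numbers gave over 0.1, which was so for UV-B in WT (0.563, 0.517 and 0.173), for uvr8 against WT (0.591, 0.657 and 0.128) and for hy5 against WT (0.576, 0.606 and 0.330). The numbers come from the sample titles, which do not say what they stand for. Alternatives were another scaling (RLE), no count filter, the replicate number as a block, DESeq2 1.42.0, a fit of only the libraries compared, leaving out each library in turn, an estimated correlation for lists and, for the held-out shares, other selections of genes. Leaving out all libraries of 1 number was added after the data were seen.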

Results

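Polyadenylated RNA was measured by stranded sequencing in 24 libraries of the unicellular green alga Chlamydomonas reinhardtii. The libraries came from the wild-type strain CC5325 (WT) and from 3 mutant strains, called uvr8, co and hy5. Each genotype was kept under dim white light for 1 h with or without narrowband UV-B, and each of the 8 groups held 3 libraries. UVR8 is the UV-B photoreceptor of plants and green algae, and CO is a CONSTANS-like transcriptional regulator. HY5, which the series text also calls CrBlz3, is a bZIP transcription factor. The series title names LHL4, a protein related to the light-harvesting antenna, as a product of photoreceptor signalling that protects photosystem II (PSII). The design asks which transcripts respond to UV-B in WT, and how that response differs in each mutant. Libraries held 19267700 to 27686700 counts, of which the 50 most abundant genes took 23.3% to 33.9%, and 13613 genes had enough counts to be tested. Libraries of one group differed by more than counting noise in all 24 within-group pairs (chi-square per degree of freedom 21.3 to 131), so all were counted as separate samples. The labels do not say whether they came from separate cultures, so the p-values measure only the spread between these samples. Levels are given below as counts scaled to a common library size (CPM), with the mean ± SD of n = 3 libraries, and changes as log2 fold changes with their SE.

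The mutated genes were examined first. CO (Cre06.g278159) stood at 615 ± 102 CPM in WT without UV-B and at 772 ± 84.6 CPM with it, against 7.77 ± 1.18 and 9.91 ± 0.131 CPM in co (log2 fold change -6.31, SE 0.21, adjusted p = 1.54e-13 without UV-B). In uvr8 and hy5 it lay between 540.5 and 669 CPM. HY5 (Cre06.g310500) was at 0.824 ± 0.207 CPM without and 0.931 ± 0.128 CPM with UV-B in hy5, against 8.40 ± 2.58 and 162 ± 18.3 CPM in WT (log2 fold change -3.33, SE 0.48, adjusted p = 0.000149 without UV-B). UVR8 (Cre05.g230600) was lower in uvr8 than in WT by a smaller amount, at 24.6 ± 0.936 against 40.0 ± 8.77 CPM without UV-B (log2 fold change -0.70, SE 0.18, adjusted p = 0.0205) and 25.8 ± 4.69 against 30.4 ± 4.51 CPM with it. It lay at 36.8 and 37.1 CPM in co and hy5 without UV-B. The UVR8 call was lost without WT no-UV-B libraries 1 or 3 or uvr8 no-UV-B libraries 2 or 3 (adjusted p = 0.0651 to 0.145), and in a fit of only the libraries compared (adjusted p = 0.124). The labels do not describe the lesion in uvr8, so the transcript level checks that label less closely than it does for co and hy5.

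One hour of UV-B raised transcripts of UV-B signalling, of photoprotection and of LHC-like proteins in WT. The signalling genes COP1 (Cre02.g085050) and SPA1 (Cre13.g602700), which encode parts of the ubiquitin ligase that acts downstream of UVR8, rose from 10.6 ± 1.98 to 77.4 ± 6.89 CPM (log2 fold change 2.86, SE 0.22, adjusted p = 1.21e-08) and from 16.8 ± 4.36 to 102 ± 10.4 CPM (log2 fold change 2.60, SE 0.19, adjusted p = 5.90e-09). HY5 rose from 8.40 ± 2.58 to 162 ± 18.3 CPM (log2 fold change 4.28, SE 0.45, adjusted p = 6.99e-07). Of the genes for qE, the rapid dissipation of absorbed light as heat, LHCSR1 (Cre08.g365900) rose from 69.1 ± 86.2 to 1723 ± 86.3 CPM (log2 fold change 4.64, SE 1.12, adjusted p = 0.00688). PSBS1 and PSBS2 went from near 0, at 0.869 ± 0.879 and 1.64 ± 2.03 CPM, to 355 ± 42.6 and 579 ± 25.1 CPM (adjusted p = 3.30e-09 and 1.60e-07). LHL4 (Cre17.g740950), the gene in the series title, rose from 15.9 ± 17.2 to 529 ± 56.1 CPM (log2 fold change 5.06, SE 0.91, adjusted p = 0.000515). The early light-inducible protein (ELIP) genes ELI2 and ELI4 went from 0.142 ± 0.1505 and 0.433 ± 0.374 CPM to 227 ± 12.9 and 208 ± 15.3 CPM (adjusted p = 9.21e-10 and 3.88e-09). ELI1 rose from 136 ± 21.9 to 936 ± 211 and ELI5 from 19.5 ± 18.5 to 255 ± 72.7 CPM (log2 fold changes 2.78 and 3.71). All of these calls held in each of the 6 fits that left out 1 WT library, where log2 fold changes ranged over 4.58 to 6.46 for LHL4, 4.09 to 6.44 for LHCSR1 and 3.22 to 4.79 for ELI5.

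LHCSR3A and LHCSR3B, near-identical copies between which reads may be split, rose from 365 to 1091 and from 396 to 1209 CPM, with smaller log2 fold changes of 1.58 (SE 0.52, adjusted p = 0.0423) and 1.61 (SE 0.47, adjusted p = 0.0248). PSBS1 and PSBS2 are likewise close copies and their separate levels are uncertain. The LHCSR3A call was lost without UV-B libraries 1 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0519 to 0.189). The LHCSR3B call was lost without UV-B library 1 or no-UV-B libraries 2 or 3 (adjusted p = 0.0873 to 0.130), and both were lost in a fit of the WT libraries alone (adjusted p = 0.0698 and 0.0564). Across the lists fixed in advance, all 5 measured qE genes and all 5 measured LHC-like and ELIP genes rose, whether adjusted over all genes or adjusted over the list alone. Of the 5 UV-B signalling genes 3 rose, and UVR8 and CO did not pass. Adjusted over the list alone 3 rose and UVR8 fell (log2 fold change -0.40, adjusted p = 0.138 over all genes and 0.0104 with the replicate number as a block). The 3 lists stood above other genes in camera, a competitive set test, at adjusted p = 4.30e-07, 4.91e-16 and 7.57e-08, and at adjusted p = 0.00535, 0.00136 and 0.00216 with an estimated correlation.

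**Figure D1:**
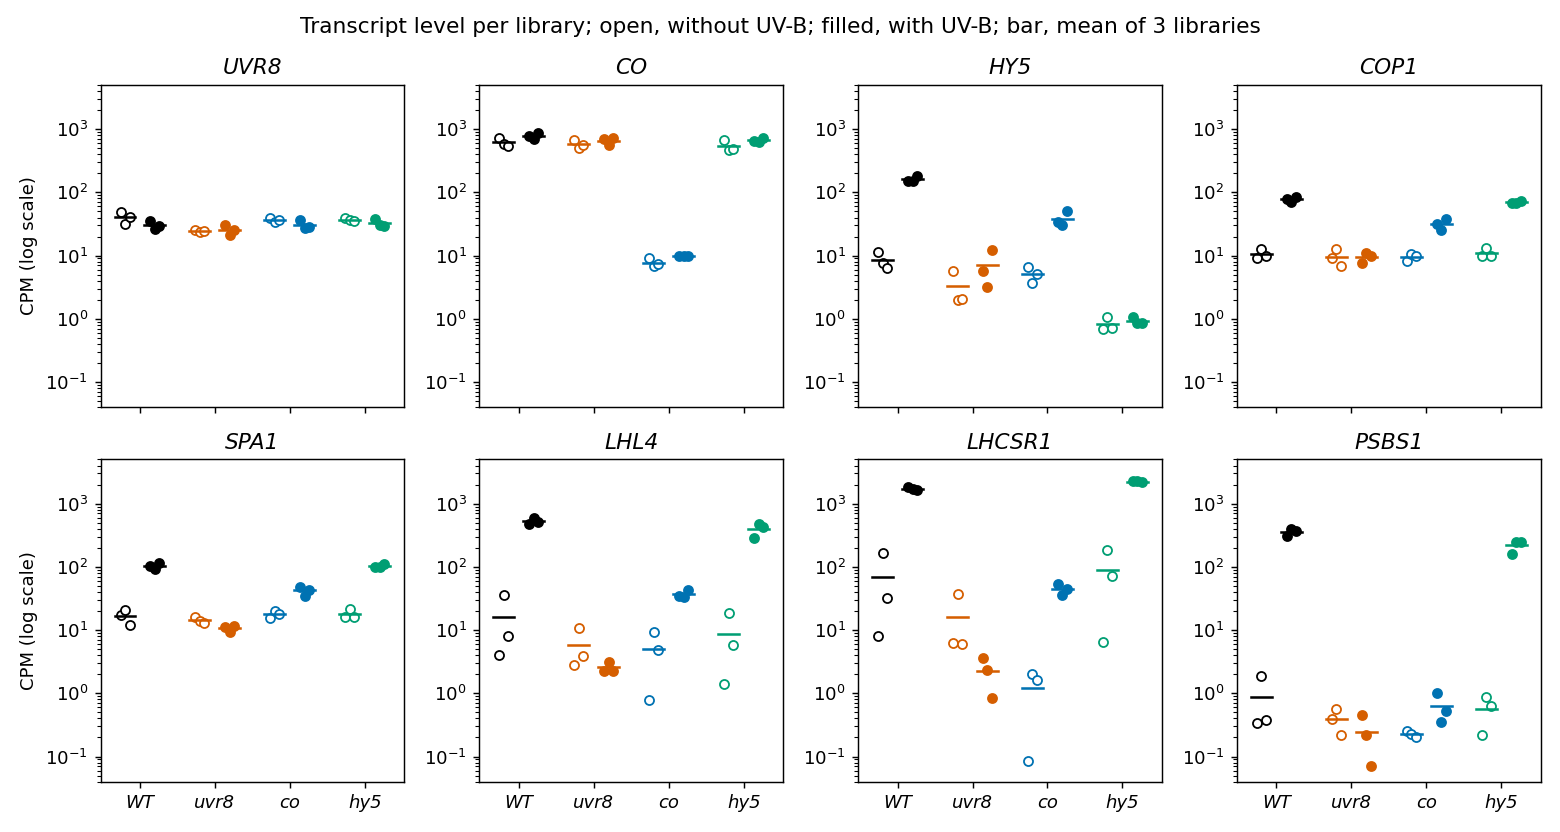
CPM (log axis) of 8 genes in each of the 24 libraries, by genotype, with open points for libraries without UV-B, filled points for libraries with UV-B and bars for group means. LHL4 reached 529 CPM on average in WT and 400.2 CPM in hy5 with UV-B, against 36.9 CPM in co and 2.56 CPM in uvr8.

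Genes for building and repairing PSII rose with UV-B in WT. FTSH2, a subunit of the thylakoid protease that degrades damaged D1 protein, rose from 554 ± 113 to 3157 ± 70.0 CPM (log2 fold change 2.51, SE 0.15, adjusted p = 7.54e-10). The PSII assembly factors HCF136 and RBD1 rose from 222 ± 44.9 to 1513 ± 219 and from 87.4 ± 14.7 to 551 ± 81.3 CPM (log2 fold changes 2.77 and 2.66). TEF5 rose from 164 ± 40.5 to 1418 ± 159 CPM (log2 fold change 3.11). Of the 11 measured PSII assembly and repair genes 7 rose and 4 did not pass, and adjusted over the list alone 8 rose and 1 fell (camera adjusted p = 4.22e-17, and adjusted p = 0.00216 with an estimated correlation). Of 5 measured carotenoid biosynthesis genes 3 rose, and 4 did adjusted over the list alone (camera adjusted p = 4.63e-08, and adjusted p = 0.00299 with an estimated correlation). The desaturase genes PDS1 and ZDS1 rose from 114 ± 6.51 to 778 ± 54.5 and from 78.3 ± 5.91 to 382 ± 7.53 CPM (log2 fold changes 2.77 and 2.29). The phytoene synthase gene PSY1 rose from 78.0 ± 14.1 to 214 ± 58.3 CPM (log2 fold change 1.46). ZEP1, for zeaxanthin epoxidase, changed by 0.47 (SE 0.19, adjusted p = 0.104) and passed with the replicate number as a block (adjusted p = 0.0163). Of 13 genes for defence against reactive oxygen species 3 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone. The list as a whole passed only with the replicate block (camera adjusted p = 0.0816 without and 0.0267 with it, and adjusted p = 0.222 with the block and an estimated correlation). GPX5, a glutathione peroxidase gene, rose from 83.7 ± 27.5 to 458 ± 42.0 CPM. VTC2, for an enzyme of ascorbate synthesis, rose from 11.2 ± 6.63 to 179 ± 28.5 CPM (log2 fold changes 2.45 and 3.99). The animal-like cryptochrome gene aCRY rose from 15.5 ± 0.436 to 53.6 ± 6.58 CPM (log2 fold change 1.79). The other 2 photoreceptor genes, PHOT1 and CPH1, changed by -0.24 and 0.25 and did not pass. As a list the photoreceptors had a camera adjusted p = 0.0320, lost with an estimated correlation (adjusted p = 0.0722) and with the replicate block (adjusted p = 0.0620). The calls of the genes in this paragraph that rose held in each fit leaving out 1 WT library.

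**Figure D2:**
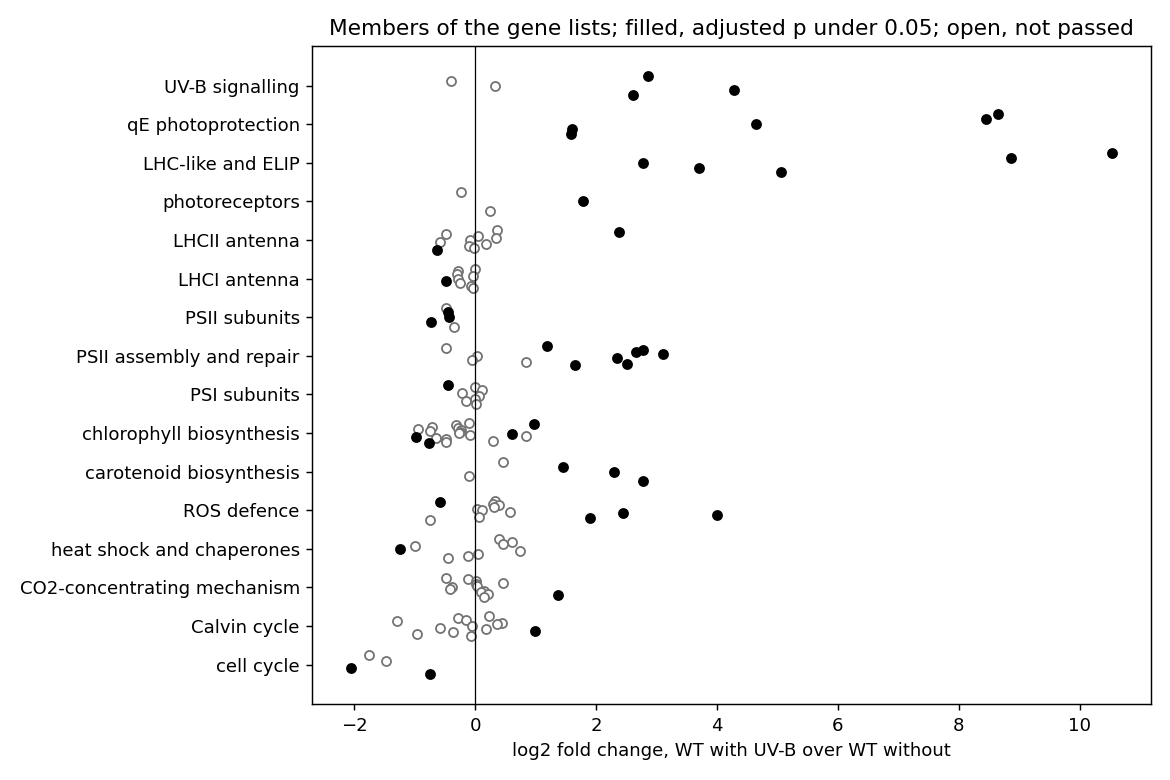
Log2 fold change with UV-B in WT (horizontal axis) for each measured gene of the 16 lists (vertical axis), where filled points passed at an adjusted p under 0.05 and open points did not. All members of the qE and LHC-like lists lie to the right of 0, and the points of the PSII subunit list lie to its left.

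Other changes in WT, most of them falls, occurred among the structural genes of the photosystems and the cell cycle genes. LHCB5, a minor antenna protein of PSII, fell from 2643 ± 223 to 1697 ± 95.6 CPM (log2 fold change -0.64). The PSII subunit genes PSBY and PSBO fell from 924 ± 46.5 to 556 ± 29.9 and from 4044 ± 138 to 2989.8 ± 294 CPM (log2 fold changes -0.73 and -0.44). LHCB7 rose from 18.7 ± 6.88 to 97.4 ± 7.30 CPM (log2 fold change 2.38). CDKA1, for a cyclin-dependent kinase, fell from 134 ± 20.7 to 80.4 ± 13.1 CPM (log2 fold change -0.74). PGK1, for phosphoglycerate kinase, and DVR1, for divinyl reductase of chlorophyll synthesis, rose from 558 ± 118 to 1111 ± 244 and from 104 ± 6.79 to 203 ± 6.43 CPM (log2 fold changes 0.99 and 0.97). These calls held when any 1 library was left out. In a fit of the WT libraries alone, those of LHCB5, PSBO, PGK1 and CDKA1 were lost (adjusted p = 0.0659, 0.174, 0.0691 and 0.0841). Of the 5 PSII subunit genes 3 fell, and 5 fell when adjusted over the list alone or with the replicate number as a block (camera adjusted p = 0.00861, and adjusted p = 0.266 with an estimated correlation). PSBP1, with a log2 fold change of -0.35 (adjusted p = 0.0566), passed with the block (adjusted p = 0.0218), with the other scaling (adjusted p = 0.0324) and with DESeq2 (adjusted p = 0.00453). Of 4 measured cell cycle genes 2 fell, and 4 fell adjusted over the list alone or with the block (camera adjusted p = 0.00861, and adjusted p = 0.224 with an estimated correlation). CYCA1 and CYCB1 went from 18.3 to 5.35 and from 33.0 to 11.8 CPM, at adjusted p = 0.0546 and 0.0718 without and 1.24e-05 and 8.21e-05 with the block, and both passed with DESeq2 (adjusted p = 0.0144 and 0.0268). Among 11 LHCII antenna genes 1 rose and 1 fell, and the list had a median log2 fold change of -0.02 but a mean of 0.13 (camera adjusted p = 0.984). Of 9 LHCI genes 1 fell, of 8 PSI subunit genes 1 fell, of 19 chlorophyll biosynthesis genes 2 rose and 2 fell, of 9 heat shock and chaperone genes 1 fell (0 adjusted over the list alone), of 13 genes of the CO2-concentrating mechanism 1 rose and of 13 Calvin cycle genes 1 rose. With the block, RBCS1, for a Rubisco subunit, fell as well (adjusted p = 0.0590 without and 0.0344 with it), as it did with DESeq2 and with the WT libraries alone (adjusted p = 0.0262 and 0.0223). LHCA6 passed with DESeq2, also downward (adjusted p = 0.0324). The 6 lists other than LHCII did not pass (camera adjusted p = 0.117 to 0.984), and for the PSI, heat shock and CO2-concentrating lists the median was above 0 while camera pointed down.

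Several further calls in WT had adjusted p from 0.00988 (CHLH1) to 0.0485 (HSP90A) in the main fit. Each was lost when any of 1 to 5 single WT libraries was left out. The fall of LHCA4 (-0.48 log2) was lost without no-UV-B libraries 1, 2 or 3 or UV-B library 1 (adjusted p = 0.0551 to 0.134). That of PSBQ (-0.45) was lost without UV-B libraries 1 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0531 to 0.0948). That of PSAN (-0.44) was lost without no-UV-B libraries 1 or 3 or UV-B libraries 2 or 3 (adjusted p = 0.0724 to 0.1397). In chlorophyll synthesis the rise of CHLH1 (0.61) was lost without UV-B library 3 (adjusted p = 0.0593). The falls of PPX1 (-0.97) and PBGD1 (-0.77) were lost without UV-B libraries 1 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0839 to 0.0984) and without UV-B libraries 1 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0545 to 0.148). The rise of MSD3 (1.91), a manganese superoxide dismutase gene, was lost without no-UV-B libraries 1 or 2 or UV-B library 3 (adjusted p = 0.0976 to 0.117). The fall of APX1 (-0.58), an ascorbate peroxidase gene, was lost without UV-B libraries 1, 2 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0595 to 0.15002). The fall of HSP90A (-1.25) was lost without UV-B libraries 1, 2 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.0653 to 0.146) and with the other scaling of libraries (adjusted p = 0.05004, just above the threshold). The rise of CAH3 (1.36), for the carbonic anhydrase of the thylakoid lumen, was lost without UV-B library 1 or no-UV-B libraries 2 or 3 (adjusted p = 0.0770 to 0.0796). The fall of CDKB1 (-2.06) was lost without UV-B libraries 1 or 3 or no-UV-B libraries 2 or 3 (adjusted p = 0.104 to 0.139). The log2 fold changes kept their sign in these fits, at -0.58 to -0.34 for LHCA4, -0.53 to -0.38 for PSBQ, -0.57 to -0.34 for PSAN, 0.51 to 0.72 for CHLH1, -1.29 to -0.77 for PPX1 and -0.93 to -0.66 for PBGD1. They were at 1.57 to 2.78 for MSD3, -0.68 to -0.51 for APX1, -1.45 to -1.14 for HSP90A, 1.11 to 1.70 for CAH3 and -2.91 to -1.72 for CDKB1. A fit of the WT libraries alone lost the calls of LHCA4, PSBQ, PSAN, CHLH1, PPX1, PBGD1, MSD3, APX1 and CDKB1 (adjusted p = 0.0802 to 0.227).

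Over all genes, edgeR called 2215 at an adjusted p under 0.05, of which 1439 rose and 776 fell, 837 and 387 of them by 2-fold or more. Among the 10 steepest rises, Cre07.g333050, which carried no name here, went from 0.0164 ± 0.0284 to 16.8 ± 7.36 CPM. Among the 10 steepest falls, Cre04.g226550 went from 8.29 ± 4.13 to 0.678 ± 0.449 CPM (log2 fold change -3.58). Libraries with the same number deviated together in this comparison, and with the number as a block 3872 genes were called. A fit of the 6 WT libraries alone called 911. Leaving out the WT no-UV-B library numbered 3 left 1275. The share of called genes that rose was 65.0% in the main fit and 55.1% with the block. It was 79.8% with the WT libraries alone and 75.7% without that library. On simulated counts for 13550 genes the same test recovered 40% of 2-fold and 89% of 4-fold changes in this comparison.

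In uvr8, edgeR called none of the genes that UV-B raised in WT. LHL4 went from 5.82 ± 4.38 to 2.56 ± 0.518 CPM and LHCSR1 from 16.3 ± 17.6 to 2.24 ± 1.38 CPM (adjusted p = 0.679 and 0.531), and PSBS1, PSBS2, ELI2 and ELI4 stayed under 1 CPM in both groups. COP1 stood at 9.56 ± 2.99 CPM without and 9.41 ± 1.68 CPM with UV-B, SPA1 at 14.3 ± 1.55 and 10.8 ± 1.23 CPM, and FTSH2 at 417 ± 29.1 and 376 ± 10.2 CPM. HY5 was at 3.27 ± 2.16 without and 7.11 ± 4.76 CPM with UV-B (log2 fold change 1.13, SE 0.42, adjusted p = 0.531). With edgeR, 0 of 13613 genes passed, while 1209 had an unadjusted p under 0.05 against 681 by chance. DESeq2 called 14, 9 higher and 5 lower with UV-B, among them the antenna gene LHCBM9, which also rose adjusted over the list alone. The 9 also held Cre08.g360550 and Cre15.g634650, unnamed genes that rose in WT as well (log2 fold changes 2.51 and 4.72 in WT, and 3.18 and 3.37 in uvr8). These 3 genes are exceptions to the naming rule and were picked after their values were seen. The other edgeR fits, with another scaling, without the count filter, with the replicate block or with the uvr8 libraries alone, called 0 as well. Without uvr8 UV-B library 1 edgeR called 27 genes, and without all libraries numbered 1, an alternative chosen after the data were seen, 1581. No other list member passed. Camera placed the LHCII and LHCI antenna lists higher (adjusted p = 0.000138 and 0.0391) and the heat shock, PSII assembly and LHC-like lists lower (adjusted p = 0.000138, 0.0391 and 0.0496), and all 5 calls were lost with an estimated correlation (adjusted p = 0.462 to 0.559).

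The test of the difference between uvr8 and WT covered the same genes. The UV-B effect was smaller in uvr8 for LHL4 by -6.24 (SE 1.21, adjusted p = 0.00206) on the log2 scale, for LHCSR1 by -7.51 (SE 1.55, adjusted p = 0.00355). It was smaller for COP1 by -2.88 (SE 0.30, adjusted p = 2.10e-06), for SPA1 by -3.02 (SE 0.26, adjusted p = 2.84e-07) and for HY5 by -3.15 (SE 0.59, adjusted p = 0.00146). The same held for FTSH2, HCF136, RBD1 and TEF5 (log2 differences -2.66, -2.90, -2.78 and -3.44), for PDS1, ZDS1 and PSY1 (-2.90, -2.17 and -1.42), and for GPX5, VTC2, aCRY and LHCB7 (-2.53, -4.03, -2.01 and -2.28). In the lists, 3 of 5 signalling, 3 of 5 qE (5 adjusted over the list alone), 5 of 5 LHC-like, 7 of 11 PSII assembly (8 lower and 1 higher adjusted over the list alone), 3 of 5 carotenoid, 2 of 13 reactive oxygen and 1 of 3 photoreceptor genes (2 adjusted over the list alone) had a lower effect in uvr8. Camera calls for these held with an estimated correlation (adjusted p = 0.000761 to 0.0191), except the reactive oxygen list (adjusted p = 0.0225, and adjusted p = 0.0693 with an estimated correlation). LHCB5, PSBY and PSBO, which fell in WT, had a higher effect in uvr8 (log2 differences 0.75, 0.69 and 0.56). As lists, 2 of 5 PSII subunit genes were higher, and 5 adjusted over the list alone (camera adjusted p = 0.00246, and adjusted p = 0.207 with an estimated correlation). No LHCI gene was higher, with 2 adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.458 with an estimated correlation).

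The effect differed between uvr8 and WT for 856 genes, lower in uvr8 for 723 and higher for 133. The share of called genes higher in uvr8 was 15.5% here and 6.32% with only the libraries compared. It was 26.5% with DESeq2 and 37.2% with the replicate number as a block. Of the 1439 genes that rose in WT, 705 had a significantly lower effect in uvr8, and of the 776 that fell in WT, 106 had a weaker fall. The same WT libraries chose these genes and entered the difference, which favours a weaker effect in uvr8. A fit of only the WT and uvr8 libraries called 522 and lost LHCB5, PSBY, PSBO and PGK1 (adjusted p = 0.0879 to 0.198). The PSBY call was lost without uvr8 no-UV-B libraries 2 or 3, WT no-UV-B library 3 or uvr8 UV-B library 3 (adjusted p = 0.0678 to 0.0803). The PSBO call was lost without WT no-UV-B libraries 1, 2 or 3, WT UV-B libraries 1 or 2, uvr8 no-UV-B libraries 2 or 3 or uvr8 UV-B libraries 2 or 3 (adjusted p = 0.0510 to 0.113). The ELI5 call (log2 difference -4.84) was lost without uvr8 no-UV-B library 2 (adjusted p = 0.0518).

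In co, UV-B raised some of the genes that it raised in WT. COP1 rose from 9.67 ± 1.22 to 31.3 ± 6.16 CPM, SPA1 from 17.9 ± 2.15 to 42.3 ± 6.50 CPM and HY5 from 5.11 ± 1.44 to 38.1 ± 10.3 CPM (log2 fold changes 1.69, 1.24 and 2.90, adjusted p = 0.000141, 0.000514 and 0.000514). HCF136 rose from 183 ± 20.0 to 469.6 ± 82.4 CPM, FTSH2 from 557 ± 35.8 to 1239 ± 136 CPM and TEF5 from 167 ± 15.9 to 378 ± 92.4 CPM (log2 fold changes 1.36, 1.15 and 1.18). ZDS1, PDS1, GPX5 and VTC2 had log2 fold changes of 0.88, 1.01, 1.39 and 2.31. PSBS1 stood at 0.228 ± 0.0233 CPM without and 0.624 ± 0.335 CPM with UV-B, ELI2 at 0.0330 ± 0.0324 and 0.373 ± 0.236 CPM and ELI4 at 0.0449 ± 0.0523 and 0.254 ± 0.193 CPM. LHL4 went from 5.01 ± 4.27 to 36.9 ± 5.53 CPM (log2 fold change 2.87, SE 0.84, adjusted p = 0.114), and DESeq2 called it (adjusted p = 0.0117), as it did ELI2 (adjusted p = 0.0152). LHCSR1 rose from 1.23 ± 1.02 to 44.8 ± 8.71 CPM (log2 fold change 5.15, SE 1.19, adjusted p = 0.0254), a call lost without no-UV-B libraries 1, 2 or 3 or UV-B libraries 1 or 3 (adjusted p = 0.0559 to 0.134). The calls of PSBS2, at 1.77 ± 0.390 CPM with UV-B, and of ELI1, at 203 ± 49.0 CPM, were lost without no-UV-B libraries 1, 2 or 3 or UV-B libraries 1, 2 or 3 (adjusted p = 0.0587 to 0.215) and without no-UV-B library 1 or UV-B library 1 (adjusted p = 0.0544 to 0.0680). The ELI1 call was also lost in a fit of the co libraries alone (adjusted p = 0.0645).

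By list, 3 of 5 signalling genes, 2 of 5 qE genes, 1 of 5 LHC-like genes (4 adjusted over the list alone), 6 of 11 PSII assembly genes, 2 of 5 carotenoid genes (3 adjusted over the list alone), 2 of 13 reactive oxygen genes and 1 of 3 photoreceptor genes rose in co. Camera called the signalling, LHC-like, PSII assembly and carotenoid lists with a preset and an estimated correlation (estimated adjusted p = 0.000933, 0.0208, 0.00700 and 0.0371). It called the qE list upward (adjusted p = 0.000739) and the chlorophyll list downward (adjusted p = 0.00700) only with the preset one (adjusted p = 0.0665 and 0.558 with an estimated correlation). EdgeR called 234 genes, of which 225 rose and 9 fell. A fit of the co libraries alone called 79 and DESeq2 360. Leaving out co no-UV-B library 1 or 3 or co UV-B library 3 left 136, 131 or 147. Without all libraries numbered 3, left out after the data were seen, 0 genes were called.

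The UV-B effect differed between co and WT for 238 genes, lower in co for 232 and higher for 6. This balance depended on the fit. The share of called genes higher in co was 2.52% here and 1.35% with only the libraries compared. It was 7.35% with DESeq2 and 32.3% with the replicate number as a block. PSBS1 had the lower effect in co by -7.20 (SE 0.97, adjusted p = 0.000462) on the log2 scale, SPA1 by -1.36 (SE 0.26, adjusted p = 0.00598), and FTSH2, HCF136, RBD1 and TEF5 by -1.36, -1.41, -1.54 and -1.93. ZDS1, PDS1, aCRY and LHCB7 had log2 differences of -1.41, -1.76, -1.10 and -1.54. For LHL4 the difference was -2.19 (SE 1.12, adjusted p = 0.591), and for LHCSR1 0.51 (SE 1.41, adjusted p = 0.999), so neither passed. With SE of this size, that does not show an equal response. With UV-B both stood lower on average in co than in WT, LHCSR1 at 44.8 against 1723 CPM. LHCSR1 was also lower without UV-B, at 1.23 against 69.1 CPM. The levels with UV-B were not compared between co and WT by a test. A lower effect was called for 1 of 5 signalling genes (3 adjusted over the list alone), 1 of 5 qE genes (2), 1 of 5 LHC-like genes (4), 5 of 11 PSII assembly genes (6) and 2 of 5 carotenoid genes (2), where the numbers in brackets are adjusted over the list alone. These 5 lists were called by camera with an estimated correlation too (adjusted p = 0.00767 to 0.0335). The PSII subunit and cell cycle lists, higher in co, were called only with the preset one (adjusted p = 0.00542 and 0.00338, and adjusted p = 0.266 and 0.176 with an estimated correlation). The count was 114 without WT no-UV-B library 3, 128 without co UV-B library 2, 148 with only the libraries compared and 408 with DESeq2. It was 0 without all libraries numbered 3. The call of LHCB7 was lost without WT no-UV-B library 3 (adjusted p = 0.0622).

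In hy5, UV-B raised genes of photoprotection and PSII repair as it did in WT. LHL4 rose from 8.54 ± 8.81 to 400.2 ± 97.7 CPM (log2 fold change 5.54, SE 0.94, adjusted p = 0.000331), PSBS1 went from 0.569 ± 0.329 to 219 ± 49.5 CPM and ELI2 and ELI4 reached 122 ± 29.7 and 148 ± 27.4 CPM from under 1 CPM (ELI2 log2 fold change 9.02, against 10.54 in WT). LHCSR1 rose from 88.4 ± 90.9 to 2237 ± 64.9 CPM (log2 fold change 4.66, SE 1.12, adjusted p = 0.00895), a call lost without no-UV-B library 3 (adjusted p = 0.0574). COP1 rose from 11.03 ± 2.00 to 69.3 ± 3.78 CPM and SPA1 from 18.04 ± 3.37 to 104 ± 5.96 CPM (log2 fold changes 2.65 and 2.52). FTSH2 rose from 466 ± 63.3 to 3114 ± 280.5 CPM and TEF5 from 141 ± 14.6 to 1199 ± 99.7 CPM (2.74 and 3.09). All 5 qE and all 5 LHC-like genes rose, also adjusted over the list alone, with 2 of 5 signalling, 7 of 11 PSII assembly (7, and 1 that fell, adjusted over the list alone), 4 of 5 carotenoid and 3 of 13 reactive oxygen genes. Of the PSII subunit genes 5 of 5 fell, of the LHCI genes 4 of 9 (7 adjusted over the list alone) and of the PSI subunit genes 2 of 8 (7 adjusted over the list alone). LHCB5 fell from 2658 ± 128 to 1550.5 ± 99.9 CPM and PSBO from 3929 ± 52.0 to 2628 ± 356 CPM (log2 fold changes -0.78 and -0.58). Camera calls for the rising signalling, qE, LHC-like, PSII assembly and carotenoid lists held with an estimated correlation (adjusted p = 0.000269 to 0.00523). Those for the photoreceptor, PSII subunit, LHCI, PSI, chlorophyll and cell cycle lists (adjusted p = 2.29e-05 to 0.0307) did not (adjusted p = 0.0764 to 0.453 with an estimated correlation). EdgeR called 1305 genes, 959 higher and 346 lower, against 849 in a fit of the hy5 libraries alone and 827 without hy5 no-UV-B library 3. The ELI5 call (log2 fold change 2.63, adjusted p = 0.0496) was lost without no-UV-B libraries 1 or 3 or UV-B libraries 1, 2 or 3 (adjusted p = 0.0576 to 0.184), with the other scaling (adjusted p = 0.0554) and with the hy5 libraries alone (adjusted p = 0.0767). The LHCSR3A call (log2 fold change 2.03) was lost without no-UV-B libraries 2 or 3 (adjusted p = 0.0540 to 0.0882).

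The effect differed between hy5 and WT for 4 genes, all lower in hy5, while 427 genes had an unadjusted p under 0.05 against 681 by chance and DESeq2 called 10. HY5 itself was one, with a log2 difference of -4.10 (SE 0.67, adjusted p = 0.0366). The other 3, named here after their values were seen, carried no gene name. Cre07.g349700 went from 0.507 ± 0.286 to 27.9 ± 12.1 CPM in WT and from 4.63 ± 0.210 to 7.55 ± 1.81 CPM in hy5 (log2 difference -5.05). Cre07.g318300 went from 1.45 ± 0.729 to 9.48 ± 1.27 and from 12.9 ± 2.05 to 15.6 ± 4.61 CPM (log2 difference -2.44). Cre05.g239700 went from 2.13 ± 0.347 to 5.15 ± 1.31 and from 4.79 ± 1.05 to 3.44 ± 0.287 CPM (log2 difference -1.75). In WT without UV-B all 3 stood lower than in each of the mutants, at 5.72, 9.48 and 5.39 CPM in uvr8 and 3.01, 10.7 and 3.60 CPM in co. The effect on Cre07.g349700 and Cre07.g318300 was lower than in WT in uvr8 (log2 differences -6.73 and -3.47) and in co (-5.35 and -2.20) as well, so these differences are not particular to hy5. Cre07.g349700 passed in each fit leaving out 1 of the 12 libraries. The HY5 call was lost without WT UV-B libraries 1 or 3, hy5 no-UV-B libraries 1, 2 or 3, hy5 UV-B libraries 1, 2 or 3 or WT no-UV-B libraries 2 or 3 (adjusted p = 0.0606 to 0.219). That of Cre07.g318300 was lost without WT UV-B libraries 1 or 3, hy5 no-UV-B libraries 1, 2 or 3, WT no-UV-B libraries 2 or 3 or hy5 UV-B libraries 2 or 3 (adjusted p = 0.0601 to 0.224). The Cre05.g239700 call was lost without WT no-UV-B libraries 1, 2 or 3, hy5 no-UV-B libraries 1, 2 or 3, hy5 UV-B libraries 1, 2 or 3 or WT UV-B library 3 (adjusted p = 0.0760 to 0.248) and without the count filter (adjusted p = 0.0587). A fit of only the WT and hy5 libraries lost Cre07.g318300 and Cre05.g239700 (adjusted p = 0.603 and 0.798). With 1 library left out, 1 to 7 genes were called, 2 with only the libraries compared, and 0 without all libraries numbered 3. On simulated counts this test recovered 12% of 2-fold and 62% of 4-fold differences among 13554 genes, so differences of these sizes could be missed. For LHL4 the difference was 0.49 (SE 1.10, adjusted p = 1.00), for PSBS1 -0.08 (SE 0.77, adjusted p = 1.00) and for COP1 -0.21 (SE 0.30, adjusted p = 1.00). No list member other than HY5 passed. Camera placed the signalling, LHCII, LHCI and PSI lists lower in hy5 (adjusted p = 0.00141 to 0.0298), and none with an estimated correlation (adjusted p = 0.275 to 0.724). The signalling list holds HY5, the mutated gene, at a log2 difference of -4.10, so its call says little about the other members.

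Between the hy5 and co mutants, which share no library, the UV-B effect differed for 129 genes, higher in hy5 for 128 and lower for 1. PSBS1 had the larger effect in hy5 by 7.11 (SE 0.97, adjusted p = 0.000757) on the log2 scale, and FTSH2, HCF136, RBD1, TEF5 and ZDS1 by 1.59, 1.32, 1.399, 1.91 and 1.12. SPA1 had a difference of 1.28 (SE 0.26, adjusted p = 0.0132), lost without co UV-B library 2 or hy5 no-UV-B library 3 (adjusted p = 0.0604 to 0.0615). A higher effect in hy5 was called for 5 of 11 PSII assembly genes (6 adjusted over the list alone), 2 of 5 carotenoid genes (3), 1 of 5 qE genes (4) and 1 of 5 LHC-like genes (4), with list-alone numbers in brackets. Camera called these 4 lists upward and the PSII subunits downward with an estimated correlation (adjusted p = 0.000562 to 0.0353). It called the LHCII, LHCI, PSI and cell cycle lists downward only with the preset one (adjusted p = 9.34e-07 to 0.0288, and adjusted p = 0.159 to 0.373 with an estimated correlation). The count was 77, 79 and 85 without hy5 no-UV-B library 3, co UV-B library 2 and hy5 UV-B library 2, and 237 with DESeq2. It was 0 without all libraries numbered 3 and 10 without those numbered 2.

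**Figure D3:**
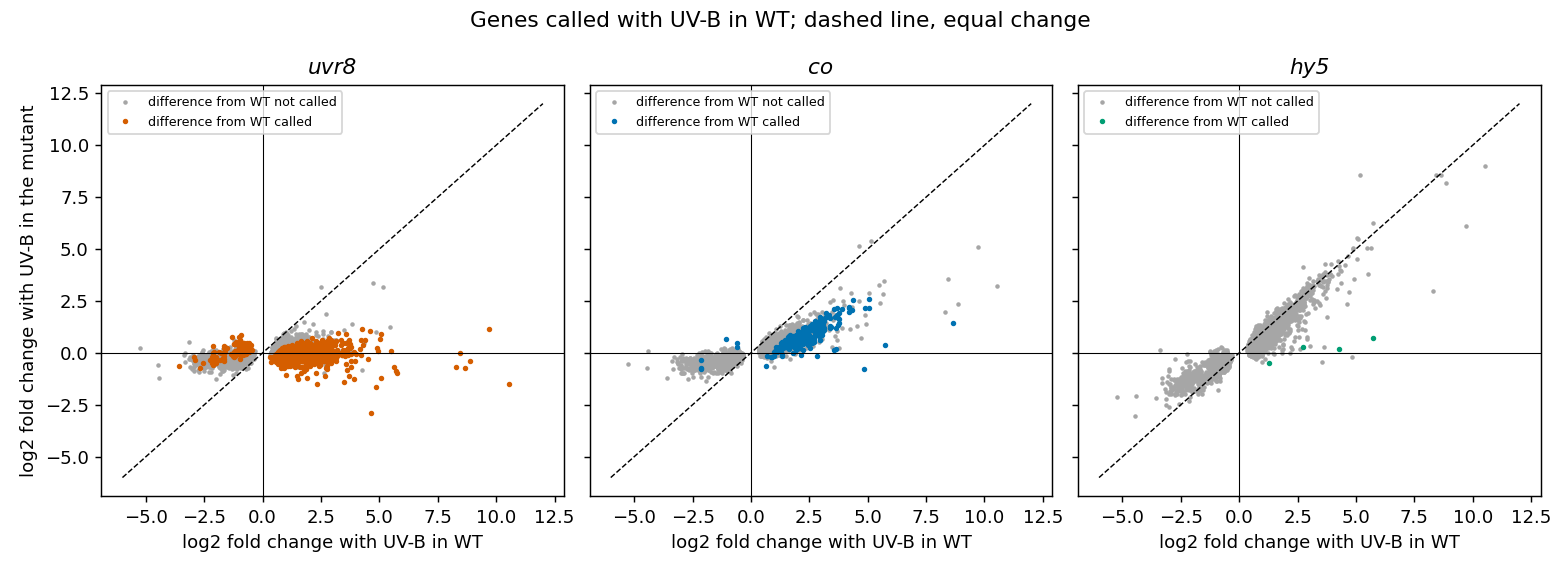
Log2 fold change with UV-B in each mutant (vertical axis, a panel per mutant) against that in WT (horizontal axis) for the 2215 genes called in WT, with coloured points where the difference from WT was called and a dashed line where both are equal. Of the genes that rose in WT, 705, 232 and 4 had a significantly weaker rise in uvr8, co and hy5. The same WT libraries chose the genes and entered these differences, which favours a weaker rise in the mutants.

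The size of the response left in each mutant was measured on libraries not used to choose the genes. For each replicate number, genes changed at least 2-fold in WT were chosen without the libraries of that number, and their median change was read in those libraries. Rising genes (461 to 965 per number) rose by 1.71 ± 0.33 on the log2 scale in WT (SD, n = 3). The mutants had 0.708% ± 7.01 (uvr8), 37.4% ± 4.28 (co) and 85.5% ± 10.6 (hy5) of that change. For falling genes (40 to 590 per number), whose WT fall was 1.402 ± 0.26, the shares were 22.3% ± 15.5, 40.9% ± 19.03 and 67.3% ± 11.6. With 3 values against 3, an exact test cannot give a p under 0.1, so these shares are descriptive. The lists of called genes overlapped between genotypes without sharing a library. They do share an estimate of the spread, so genes of small spread can pass in several genotypes. The numbers for independent lists are therefore only a rough reference. Of the 225 genes that rose in co, 224 also rose in WT (23.8 for independent lists), and of the 959 that rose in hy5, 872 did (101). Of those that fell, 8 of 9 in co and 240 of 346 in hy5 also fell in WT (0.513 and 19.7 for independent lists). Of the genes that rose in WT, 55.8% had a positive fold change in uvr8, 93.5% in co and 96.3% in hy5. Of those that fell in WT, 75.1%, 94.2% and 97.8% had a negative one.

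**Figure D4:**
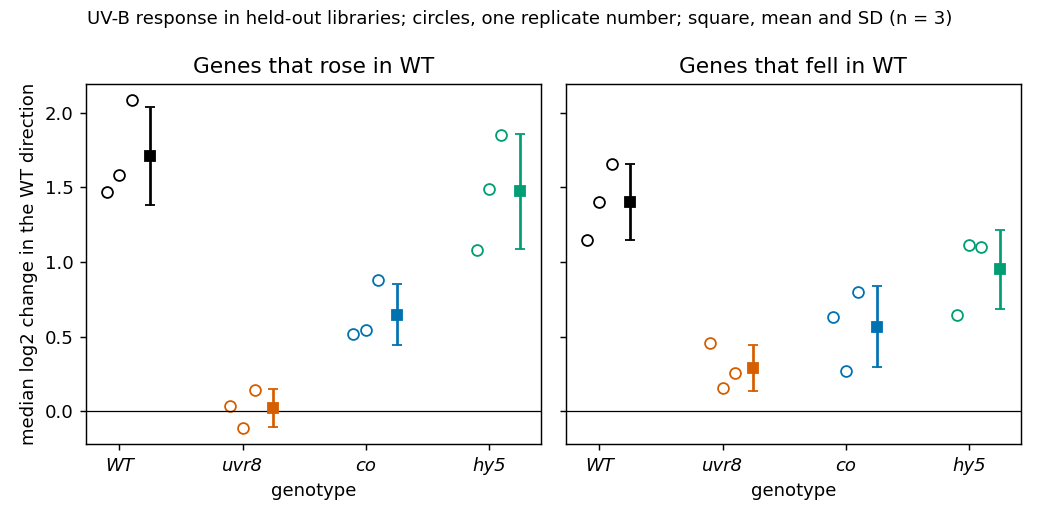
Median log2 change with UV-B in the WT direction (vertical axis) in each genotype (horizontal axis), for genes rising and falling in WT. The libraries measured were held out from choosing the genes. Circles stand for a replicate number each, and a square with a bar for the mean ± SD of 3. For rising genes the means were 1.71, 0.0217, 0.649 and 1.47 in WT, uvr8, co and hy5.

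Without UV-B, HSP22E, HSP22F, DEG1C and VIPP2 were higher in uvr8 than in WT. HSP22E and HSP22F, near-identical genes for small heat shock proteins of the plastid, stood at 300.1 ± 249 and 347 ± 306 CPM against 4.69 ± 1.97 and 3.70 ± 1.73 CPM (log2 fold change 5.995, SE 0.99, adjusted p = 0.000715 and log2 fold change 6.54, SE 1.13, adjusted p = 0.00107). DEG1C, a plastid protease gene, and VIPP2 stood at 228 ± 108 and 121 ± 114 CPM against 16.4 ± 9.28 and 8.35 ± 6.68 CPM (log2 fold changes 3.79 and 3.85), and APX1 at 296 ± 30.6 against 139 ± 13.7 CPM (1.09). The first 4 of these genes were singled out after their values were seen, and the lists of PSII assembly and of reactive oxygen genes, which hold DEG1C, VIPP2 and APX1, did not pass (camera adjusted p = 0.620 and 0.529). HY5 had a log2 fold change of -1.36 (SE 0.42, adjusted p = 0.0670) in uvr8 and passed with the replicate block (adjusted p = 0.0184) and with DESeq2 (adjusted p = 0.0264). LHL4 stood at 5.82 ± 4.38 against 15.9 ± 17.2 CPM (adjusted p = 0.361). Of 9 heat shock genes 2 were higher (3 adjusted over the list alone, camera adjusted p = 0.000317, and adjusted p = 0.516 with an estimated correlation). With the replicate block camera also called the cell cycle and CO2-concentrating lists (0.000644 and 0.0164 as adjusted p, against 0.105 and 0.105 without it). Both calls were lost with the block and an estimated correlation (adjusted p = 0.410 and 0.647). EdgeR called 726 genes, 455 higher and 271 lower in uvr8, and 2173 with the replicate number as a block, by which these libraries deviated together. The lowest of all in uvr8 included Cre06.g295600, unnamed here, at 0.0838 ± 0.0385 against 24.1 ± 4.45 CPM. A fit of only the libraries compared called 352 and DESeq2 1216. Leaving out WT no-UV-B library 1 or 3 or uvr8 no-UV-B library 2 or 3 left 437, 435, 379 or 435. The VIPP2 call was lost without WT no-UV-B libraries 1 or 3 or uvr8 no-UV-B library 2 (adjusted p = 0.0530 to 0.0654) and with only the libraries compared (adjusted p = 0.103). SEBP1, for a Calvin cycle enzyme, was lower in uvr8 (log2 fold change -0.67, SE 0.17, adjusted p = 0.0214), a call lost without WT no-UV-B libraries 1 or 3 or uvr8 no-UV-B libraries 1, 2 or 3 (adjusted p = 0.0501 to 0.122) and with only the libraries compared (adjusted p = 0.0971).

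Without UV-B, LHCSR1 and PSBS2 of the qE genes and 3 Calvin cycle genes were lower in co than in WT. LHCSR1 stood at 1.23 ± 1.02 against 69.1 ± 86.2 CPM in WT (log2 fold change -5.77, SE 1.22, adjusted p = 0.00912), a call lost without WT no-UV-B library 2 (log2 fold change -3.97, adjusted p = 0.0580) and in a fit of only these libraries (adjusted p = 0.0927). PSBS2 stood at 0.147 ± 0.0557 against 1.64 ± 2.03 CPM (log2 fold change -3.48, SE 0.88, adjusted p = 0.0325), a call lost without co no-UV-B libraries 1, 2 or 3 or WT no-UV-B library 2 (adjusted p = 0.0761 to 0.330). Its log2 fold change was -1.69 without WT no-UV-B library 2, in which LHCSR1 stood at 168 CPM against 8.01 and 31.6 CPM in the other 2. SEBP1, for sedoheptulose bisphosphatase, stood at 338 ± 46.9 against 549 ± 88.6 CPM and TPIC1, for triose phosphate isomerase, at 134 ± 6.24 against 195 ± 12.2 CPM (log2 fold changes -0.70 and -0.55). These calls were lost without WT no-UV-B libraries 1 or 3 or co no-UV-B libraries 2 or 3 (adjusted p = 0.0534 to 0.164) and without WT no-UV-B libraries 1, 2 or 3 or co no-UV-B libraries 1, 2 or 3 (adjusted p = 0.0517 to 0.117). GAP3, a gene outside the naming rule that is given here as the third call, had a log2 fold change of -0.59 (SE 0.14, adjusted p = 0.0282). It was lost without WT no-UV-B libraries 1 or 2 or co no-UV-B libraries 2 or 3 (adjusted p = 0.0681 to 0.162) and without the count filter (adjusted p = 0.0516). With only the libraries compared, none of the 3 was called (adjusted p = 0.136, 0.138 and 0.135 for SEBP1, TPIC1 and GAP3). Of 5 qE genes 2 were lower (5 adjusted over the list alone) and of 13 Calvin cycle genes 3 (10 adjusted over the list alone). Camera called both lists, and the signalling list that holds CO, with an estimated correlation (adjusted p = 0.0480, 0.0108 and 0.000823). The LHC-like list, lower, and the cell cycle list, higher, were called only with the preset one (adjusted p = 0.0471 and 0.0469, and adjusted p = 0.490 for both with an estimated correlation). EdgeR called 445 genes, 308 higher and 137 lower in co, against 242 with only the libraries compared and 803 with DESeq2. Leaving out WT no-UV-B library 1, 2 or 3 or co no-UV-B library 2 or 3 left 241, 292, 293, 224 or 276.

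In hy5 without UV-B, LHL4 stood at 8.54 ± 8.81 CPM and LHCSR1 at 88.4 ± 90.9 CPM (adjusted p = 0.601 and 0.891 against WT). CYCB1, for a cyclin, was higher at 186 ± 78.3 against 33.0 ± 16.7 CPM (log2 fold change 2.50, SE 0.56, adjusted p = 0.0109), a call lost without WT no-UV-B library 1 (adjusted p = 0.0569) and with only the libraries compared (adjusted p = 0.0637). It was also called higher in uvr8 (log2 fold change 2.39, SE 0.55, adjusted p = 0.0125) and in co (log2 fold change 2.07, SE 0.55, adjusted p = 0.0417). These calls were lost without WT no-UV-B library 1 or uvr8 no-UV-B library 2 (adjusted p = 0.0691 to 0.0792) and without WT no-UV-B libraries 1, 2 or 3 or co no-UV-B libraries 2 or 3 (adjusted p = 0.0738 to 0.186), and both with only the libraries compared (adjusted p = 0.0650 and 0.0833). SEBP1 had a log2 fold change of -0.60 (SE 0.17, adjusted p = 0.0469), lost without WT no-UV-B libraries 1 or 3 or hy5 no-UV-B libraries 1, 2 or 3 (adjusted p = 0.0614 to 0.210), without the count filter (adjusted p = 0.0578) and with only the libraries compared (adjusted p = 0.194). GAP3 had one of -0.59 (SE 0.14, adjusted p = 0.0206), lost without WT no-UV-B libraries 1 or 2 or hy5 no-UV-B libraries 2 or 3 (adjusted p = 0.0545 to 0.103) and with only the libraries compared (adjusted p = 0.136). Of 13 Calvin cycle genes 2 were lower, 4 adjusted over the list alone and 6 with the replicate block (camera adjusted p = 0.000664, and adjusted p = 0.0851 with an estimated correlation). Of 4 cell cycle genes 1 was higher, and 3 adjusted over the list alone or with the block (camera adjusted p = 0.0399, and adjusted p = 0.811 with an estimated correlation). The CO2-concentrating list, with no member called, was lower (camera adjusted p = 0.0255, and adjusted p = 0.927 with an estimated correlation). EdgeR called 580 genes, 403 higher and 177 lower, 2128 with the replicate number as a block, 266 with only the libraries compared and 1055 with DESeq2. Leaving out hy5 no-UV-B library 2 or 3 left 374 or 346.

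Part of the baseline differences was shared between mutants, which were all compared with the same 3 WT libraries. Of the 726 genes called in uvr8, 437 were called in uvr8 alone, against 114 of 445 in co alone and 179 of 580 in hy5 alone. Cre10.g421350, unnamed here and among the largest rises in each, stood at 2.21 ± 0.996 CPM in WT and at 97.7 ± 9.79, 57.8 ± 6.12 and 109 ± 21.8 CPM in uvr8, co and hy5. Uvr8 and co shared 185 higher and 24 lower genes (10.3 and 2.73 for independent lists), uvr8 and hy5 236 and 45 (13.5 and 3.52), and co and hy5 261 and 62 (9.12 and 1.78). Across genes, the log2 fold changes correlated at 0.549, 0.603 and 0.844 in the same order, and genes are not independent replicates. The correlations were 0.512, 0.509 and 0.516 in 10 simulations of unchanged groups against a shared simulated WT group. The covariances were 0.254, 0.304 and 0.366 against simulated values of 0.0740, 0.0742 and 0.0747. In these simulations the highest number of genes called in both mutants of a pair was 0 higher and 0 lower. They held no real difference of a mutant from WT without UV-B. Each gene was drawn separately in each library, so shifts shared by many genes, which the real libraries showed by number, were absent. The simulations may therefore understate what shared controls produce. The WT libraries are too few to split, so part of the overlap may still come from the shared controls.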

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

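The tests of other splits of the libraries for the 7 comparisons of 2 groups, and all tests of the 3 patterns below, were chosen after the results were seen. The results listed here stood out because the UV-B effect differed between genotypes in the test of the difference itself. The effect in uvr8 differed from that in WT for 856 genes. The log2 differences (uvr8 minus WT) were COP1 -2.88, SPA1 -3.02 and HY5 -3.15 in signalling, LHCSR1 -7.51, PSBS1 -9.38 and PSBS2 -8.45 in qE. They were LHL4 -6.24, ELI1 -3.09, ELI2 -12.05, ELI4 -9.25 and ELI5 -4.84 among LHC-like genes and FTSH2 -2.66, HCF136 -2.90, RBD1 -2.78 and TEF5 -3.44 in PSII assembly. In carotenoid synthesis they were ZDS1 -2.17, PDS1 -2.90 and PSY1 -1.42, and in defence against reactive oxygen GPX5 -2.53 and VTC2 -4.03. They were aCRY -2.01, LHCB7 -2.28, DVR1 -1.04 and PGK1 -1.002 for other genes and positive for LHCB5 0.75, PSBY 0.69 and PSBO 0.56. The PGK1 call was lost without WT no-UV-B libraries 1 or 3, uvr8 UV-B libraries 1, 2 or 3, WT UV-B libraries 2 or 3 or uvr8 no-UV-B libraries 2 or 3 (adjusted p = 0.0507 to 0.0963) and with only the libraries compared (adjusted p = 0.0879). With only the libraries compared those of LHCB5, PSBY and PSBO were lost too (adjusted p = 0.112, 0.1399 and 0.198). The ELI5, PSBY and PSBO calls were lost without single libraries at adjusted p of up to 0.0518 (uvr8 no-UV-B library 2), 0.0803 (uvr8 no-UV-B library 2) and 0.113 (uvr8 no-UV-B library 3).

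The effect in co differed from that in WT for 238 genes, with log2 differences of SPA1 -1.36, PSBS1 -7.20, ELI1 -1.50, aCRY -1.10 and LHCB7 -1.54, FTSH2 -1.36, HCF136 -1.41, RBD1 -1.54 and TEF5 -1.93, and ZDS1 -1.41, PDS1 -1.76 and PGK1 -1.13. The ELI1 call was lost without WT UV-B libraries 1 or 3, WT no-UV-B libraries 2 or 3, co no-UV-B libraries 2 or 3 or co UV-B libraries 2 or 3 (adjusted p = 0.0502 to 0.122). That of PGK1 was lost without WT no-UV-B libraries 1 or 3, co no-UV-B libraries 1, 2 or 3, co UV-B libraries 1, 2 or 3 or WT UV-B libraries 2 or 3 (adjusted p = 0.0607 to 0.132) and with only the libraries compared (adjusted p = 0.0971). That of LHCB7 was lost without WT no-UV-B library 3 (adjusted p = 0.0622). The effect in hy5 differed from that in WT for 4 genes, at HY5 -4.10, Cre07.g349700 -5.05, Cre07.g318300 -2.44 and Cre05.g239700 -1.75. Of these Cre07.g349700 alone held in every fit that left out 1 library. The others were lost at adjusted p up to 0.219 (HY5, hy5 no-UV-B library 2), 0.224 (Cre07.g318300, WT no-UV-B library 3) and 0.248 (Cre05.g239700, WT no-UV-B library 1), and the last 2 with only the libraries compared (adjusted p = 0.603 and 0.798). The effect in hy5 differed from that in co for 129 genes, at SPA1 1.28, PSBS1 7.11 and ELI1 1.59, FTSH2 1.59, HCF136 1.32, RBD1 1.399 and TEF5 1.91, and ZDS1 1.12 and PDS1 1.26. The ELI1 call was lost without hy5 no-UV-B libraries 1 or 3, hy5 UV-B libraries 1, 2 or 3, co no-UV-B libraries 2 or 3 or co UV-B libraries 2 or 3 (adjusted p = 0.0570 to 0.130). That of PDS1 was lost without co no-UV-B libraries 1, 2 or 3, hy5 no-UV-B libraries 1 or 3, hy5 UV-B libraries 1, 2 or 3 or co UV-B libraries 2 or 3 (adjusted p = 0.0622 to 0.139). That of SPA1 was lost without co UV-B library 2 or hy5 no-UV-B library 3 (adjusted p = 0.0604 to 0.0615).

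For the 4 differences of effects, 100 splits of the 12 libraries were compared, the real one included. As many genes as in the real split were called in 9 splits for uvr8 (real 856, highest other 3335), 12 for co (238, 3310), 8 for hy5 (4, 2359) and 7 for hy5 against co (129, 457). By this count chance is not excluded. The splits that called several times the real number point to a structure of the samples. Of the other splits that called as many, 8 of 8 for uvr8, 10 of 11 for co, 2 of 7 for hy5 and 6 of 6 for hy5 against co kept the UV-B libraries together by genotype, and so measured the difference between genotypes. For uvr8, co and hy5 against co the count therefore says little about chance. For the 7 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and the highest other counts were 2215 and 4 for WT with UV-B, 234 and 0 for co, 1305 and 0 for hy5, and 726, 445 and 580 with 0 in other splits for uvr8, co and hy5 without UV-B. For uvr8 with UV-B all 10 splits, the real one included, called 0, and in the other 6 comparisons 1 split, the real one, called as many. In the 3 comparisons whose numbers pair the libraries, the 3 other splits that part all 3 pairs called 0 genes. The split with 4 calls kept the pairs numbered 1 and 2 together, on opposite sides.

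The genes HSP22E, HSP22F, VIPP2 and DEG1C were high in uvr8 libraries with and without UV-B. For each of them 5 of the 6 uvr8 libraries lay above the highest of the 18 others. The libraries without UV-B are among the 5, and the genes were singled out because they were higher there. Of the uvr8 libraries with UV-B, which that comparison did not use, those numbered 1 and 2 lay above as well. This argues against 1 aberrant library. HSP22E and HSP22F are close copies, and both were chosen because they were higher in uvr8 without UV-B. Reads moved between the pair could not raise both. Their summed level in the lowest uvr8 library without UV-B was 14.6 times the WT mean. That followed from the choice and adds no separate support. The exception among the 6 libraries was uvr8 UV-B library 3, at 5.36, 4.57, 5.69 and 22.4 CPM for HSP22E, HSP22F, VIPP2 and DEG1C. In the other 5, HSP22E ranged from 60.9 to 558 CPM. A constant property of the strain would put all 6 uvr8 libraries above the 18 others. With 5 of 6 there and the exception resting on 1 library, the levels do not decide about it. Whether the high levels come from the loss of UVR8 or from another lesion stays open with 1 strain.

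The 3 mutants shared differences from WT without UV-B, with 203 genes called the same way in all 3 and 437, 114 and 179 called in uvr8, co and hy5 alone. Differences from WT in co and hy5 that share no library correlated across genes at 0.655 or more. The pairs with uvr8 did so at 0.3997 to 0.476. These set a mutant without UV-B beside another with it, each against WT. The WT libraries with and without UV-B deviated together by number, at 0.563, 0.517 and 0.173. A deviation common to both WT groups could therefore raise these correlations. They argue against the shared libraries alone, and cannot decide about such a common deviation. With 1 of the 3 WT libraries left out, at least 142 genes were called the same way in all 3 mutants. Of these at least 140 were among the 203, which argues against 1 WT library as the cause. With UV-B 192 of the 203 genes kept the direction in all 3 mutants. A background common to the mutant strains and a role of the pathway itself stay open for these 203 genes, because each mutation is represented by 1 strain.

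Genes that fell with UV-B in WT were lower in libraries numbered 1, with a median of -0.96 to -0.31 on the log2 scale against the other 2 in 8 of 8 groups, and higher in libraries numbered 2 (0.36 to 0.95). In the 4 groups of 8 where library 1 was not the deepest, these genes were lower in it all the same, at -0.63 ± 0.18 (SD), which argues against library size as the whole cause. The shift occurred in 6 of the 6 mutant groups, which a culture or batch shared by libraries of 1 number could produce. The 4 measured cell cycle genes were lower in library 1 in 8 of 8 groups, which a lower share of dividing cells in these libraries could produce. These 2 (6 of 6 and 8 of 8) stay open as hypotheses, since the labels do not say what the number stands for.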

How the results depend on the processing

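The alternatives that left out all libraries of 1 number were chosen after the data were seen, and the others before. Dropping the count filter and the RLE scaling kept every count of called genes within 1.5 times. No call of a named gene turned its direction under the alternatives chosen before. The held-out shares moved by less than 1 SD, although that of rising genes in uvr8, near 0 throughout, went from 0.708% to -0.436% when genes were chosen at 4-fold.

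With the replicate number as a block, the counts were 3872 for WT with UV-B, 468 for co with UV-B and 2617 for hy5 with UV-B. They were 2003 for the uvr8 and WT difference, 801 for the co and WT difference, 9 for the hy5 and WT difference and 253 for the hy5 and co difference, and 2173 for uvr8 without UV-B, 1812 for co without UV-B and 2128 for hy5 without UV-B. The block gave 0 calls for uvr8 with UV-B as well. Among named genes it also called LHL4 in co (adjusted p = 0.00277), and it changed no other call than those given with the results. The number pairs the libraries in 3 of the 7 comparisons of 2 groups, and 21 of 24 libraries, not all, correlated best with a library of their own number.

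With only the libraries compared, which leaves fewer libraries to estimate the spread, the counts were 911 for WT with UV-B, 79 for co with UV-B and 849 for hy5 with UV-B. They were 522 for the uvr8 and WT difference, 148 for the co and WT difference and 2 for the hy5 and WT difference, and 352 for uvr8 without UV-B, 242 for co without UV-B and 266 for hy5 without UV-B. DESeq2 gave 14 for uvr8 with UV-B, 360 for co with UV-B, 408 for the co and WT difference, 10 for the hy5 and WT difference and 237 for the hy5 and co difference. It gave 1216 for uvr8 without UV-B, 803 for co without UV-B and 1055 for hy5 without UV-B, and the cause was not tested. With an estimated correlation in camera, the numbers of lists called were 5 for WT with UV-B, 0 for uvr8 with UV-B, 5 for hy5 with UV-B, 0 for the hy5 and WT difference and 5 for the hy5 and co difference. They were 0 for uvr8 without UV-B, 3 for co without UV-B and 0 for hy5 without UV-B. The ranges without 1 library and without all libraries of 1 number were 1275 to 2227 and 531 to 3081 for WT with UV-B, 0 to 27 and 0 to 1581 for uvr8 with UV-B, 131 to 214 and 0 to 771 for co with UV-B, and 827 to 1398 and 366 to 2625 for hy5 with UV-B. They were 608 to 1116 and 224 to 1387 for the uvr8 and WT difference, 114 to 221 and 0 to 213 for the co and WT difference, 1 to 7 and 0 to 2 for the hy5 and WT difference, and 77 to 136 and 0 to 140 for the hy5 and co difference. For the mutants against WT they were 379 to 883 and 133 to 941 for uvr8 without UV-B, 224 to 330 and 85 to 543 for co without UV-B, and 346 to 550 and 135 to 869 for hy5 without UV-B, and the cause was not tested. Of the results for named genes with the RLE scaling, without the count filter, with the block, with DESeq2 and with only the libraries compared, 909 kept their side of the threshold, 41 lost it and 18 gained it. Fits that left out 1 library are not in these 3 numbers. Depth limits genes near 0 counts, such as PSBS1, PSBS2, ELI2 and ELI4 without UV-B, whose fitted differences are large and imprecise.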

Other observations

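No test in this part was run beyond those above, and the values below were picked after they were seen. Without UV-B, LHL4 differed strongly between libraries of one group and was higher in those numbered 2. It stood at 35.6 CPM in WT library 2 against 3.98 and 7.99 CPM in libraries 1 and 3. In the same order it was at 10.8 against 2.77 and 3.86 CPM in uvr8, at 9.33 against 0.796 and 4.92 CPM in co, and at 18.4 against 1.38 and 5.87 CPM in hy5. LHCSR1 stood at 168 CPM in WT library 2 against 8.01 and 31.6 CPM.

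LHL4 and LHCSR1 stood at higher levels in co with UV-B than PSBS1, PSBS2, ELI2 and ELI4. They were at 36.9 and 44.8 CPM, against 0.624, 1.77, 0.373 and 0.254 CPM for the others, whereas in WT all 6 lay between 208 and 1723 CPM. The log2 fold changes in co did not part them so, at 2.87 and 5.15 against 1.45, 3.58, 3.24 and 2.34, 4 of which did not pass with edgeR. Without UV-B the others lay at 0.0330 to 0.228 CPM in co, against 5.01 and 1.23 CPM for LHL4 and LHCSR1. COP1 and HY5 reached 31.3 and 38.1 CPM in co, against 77.4 and 162 CPM in WT. Whether these genes differ from each other in their need for CO was not tested.

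Cre06.g295600, which carries no name here, was close to silent in all uvr8 libraries, at 0.0838 ± 0.0385 CPM without and 0.0270 ± 0.0238 CPM with UV-B. It lay between 22.6 and 25.9 CPM on average in the other 6 groups. It was the 1 gene whose highest uvr8 library lay at least 20 times under the lowest library of the other genotypes, itself at 1 CPM or more. CO was the 1 such gene in co, and no gene met this in hy5. Cre10.g452250 and Cre17.g716026 did not meet it, but were also low on average in uvr8, at 0.845 and 0 CPM without UV-B against 41.7 and 1.93 CPM in WT.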
